A study of Homo sapiens and Mus musculus with 32 samples.

How the data were processed

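RNA sequencing of polyA-selected RNA measured expression in human cells with TP53 (WT) or without it (TP53KO) at several stages of trophoblast development. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was enriched on beads, and cDNA was ligated to adapters and amplified by PCR. The series lists 32 samples in 16 groups of 2 (28 human and 4 mouse), which the series description calls biological duplicates. No source says whether the duplicates came from separate cultures or clones, so the spread between them may be technical. P values rest on that spread, pooled over the groups fitted and moderated across genes by both edgeR and limma. Very small p values thus draw on the spread of many genes, not on the libraries of a group alone. Groups were taken from the labels, and each used column was matched to a sample by stage, genotype and replicate number, which left 18 used columns in 9 groups.

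Per the submitters' processing notes, RSEM and the builds hg38 and mm10 were used, with no roles or versions given. The aligner and the annotation are not given in the sources used here. For EPSC and D7 the authors deposited estimated counts per gene with no normalisation visible in the values, of which 6.93% of those above 0 were not whole. For EVT D3 and EVT D6 the deposited signal values are normalised counts by their file names. Each column was whole reads times 1 factor per library, with 100% of values within 0.01 reads of a whole number. Genes low in counts had been removed by a rule that is not stated. For TSC the deposited values are TPM (transcripts scaled to a fixed total), each column summing to about 1.0 in units of 1e+06. A further 22 deposited columns were not used because they could not be given to a sample from the labels: 8 in the estimated count table, 10 in the TPM table and 4 in the mouse table. The D2, D4, TSC TP53KO and mouse embryo samples were therefore not analysed here, and TSC were not compared with EPSC because their values are in another unit.

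The plan was to fit EPSC, D2, D4, D7 and TSC together, and the overlap of TP53KO effects was to cover those stages. With the columns that could be used, the joint fit held 8 libraries in 4 groups, and the overlap covered 4 comparisons (EPSC, D7, EVT D3 and EVT D6), an added result. The other tests of the comparisons, the gene lists and the rule for named genes were fixed before the data were examined, while checks of single patterns and regions were in part chosen later, as stated with each.

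Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood F test, robust, TMM normalisation) in R 4.3.3. Genes were kept by the filterByExpr rule (minimum count 10, minimum total 15). The joint fit used group as the only term, with contrasts for TP53KO against WT in EPSC and at D7, WT D7 against WT EPSC, and the difference of the TP53KO effects at D7 and in EPSC. EVT values were tested with limma 3.58.1 (eBayes with trend, robust) on log2 of the value plus 1, in genes with a mean of at least 10 in a group, keeping the authors' scaling. P values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. XIST, TSIX and Y-linked genes were left out of every test. List tests for EPSC and D7 used log2 CPM with a prior count of 2, and those for EVT the log2 values above.

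In total 24 gene lists were set, and those with at least 5 measured members were tested with limma's camera (preset correlation 0.01). This made 140 tests over 6 comparisons, adjusted over the lists of a comparison. They were TP53 targets, G2/M and mitosis, G1/S and replication, apoptosis machinery, primed pluripotency, naive pluripotency, trophectoderm and cytotrophoblast, syncytiotrophoblast, extravillous trophoblast, amnion, endoderm, primitive streak and mesoderm, neuroectoderm, mesenchyme and EMT, epithelial junctions, WNT targets, BMP and TGF-beta targets, YAP targets, hypoxia and glycolysis, ATF4 and unfolded protein response, interferon response, imprinted placental genes, mitochondrial transcripts and ribosomal proteins. Some genes are in more than 1 list, such as PGF, a TP53 target and a syncytiotrophoblast gene. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera takes its degrees of freedom from the few libraries fitted, so its p values rise even where the correlation is low. Fry tests whether a list's genes move, on balance, in a single direction, and does not set the list against other genes.

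Genes named in the text are TP53, the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 per 1e+06 of the column total in the higher group, and the 3 members of each list with the smallest adjusted p, or 3 rises, 3 falls and 2 members for WT D7 against WT EPSC and for the difference of effects. The text may leave out members of a list it summarises. Identifiers without a symbol and clone-based names were not named. HLA-G and the genes named for the overlap of the 4 comparisons are outside the rule and were chosen after their values were seen. Gene names were matched by identifier for 55469 of 56156 genes of the estimated count table, 16288 of 16397 of the EVT D3 table and 17457 of 17576 of the EVT D6 table. Positions are from GENCODE 29 on GRCh38, the assembly that hg38 names.

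A ratio against a group with 0 counts is a lower bound from a floor of 3 counts over the group, and a ratio against 1 to 3 counts carries an exact 95% interval for the ratio of counts. PCR reads are not independent molecules, so both cover counting error only. The expected overlap of independent lists is the product of the shares of genes called, times the genes tested in every comparison.

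The tests were checked on negative binomial counts simulated with the real mean levels, library sizes and common dispersion, with 100 genes changed by a log2 of 1 and 100 by a log2 of 2, up or down. For EPSC, edgeR recovered 93% of the changes of 1 and 100% of those of 2, with 7.2% of calls false, over 16710 genes. For D7 the figures were 86%, 100% and 3.1% over 16683 genes. Both simulations used mean levels over all 8 libraries and the same pooled dispersion. They therefore do not tell EPSC and D7 apart and leave out the wider spread of WT EPSC given below. Changed genes were drawn only from those above a minimum mean count. For EVT D3 limma recovered 97% and 100% with 1.5% false over 13655 genes, and for EVT D6 98% and 100% with 8.8% false over 13795 genes. Replicates were checked against counting noise: the mean chi-squared per gene was 20.6 in WT EPSC, 3.12 in TP53KO EPSC, 2.85 in WT D7 and 6.47 in TP53KO D7, and 1.97 to 3.78 in EVT groups, so that replicates varied beyond counting error.

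Alternatives were DESeq2 1.42.0, RLE or quantile normalisation, no filter, pseudocounts of 0.5 and 10, an absolute log2 change of at least 1, only the groups compared, a replicate block, edgeR and DESeq2 on reads recovered from the EVT values, and each library left out in turn. Those planned for the stages without usable columns were not run. Scaling by library total, leaving out chromosome 12 genes and all settings of the overlap were added after the data were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.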

Results

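Sequencing of polyA-selected RNA measured gene expression in human cells carrying TP53 (WT) or a knockout of it (TP53KO). The series lists 32 samples in 16 groups of 2, of which 28 are human and 4 are mouse embryos. The deposited columns that could be given to a sample without guessing cover 18 human libraries in 9 groups of 2, called biological duplicates in the series description. EPSC are a human pluripotent stem cell line of the expanded potential type, and D7 are the same WT and TP53KO cells after 7 days of differentiation, which the labels call extraembryonic cells. TSC are human trophoblast stem cells, and EVT D3 and EVT D6 are cells derived from TSC after 3 and 6 days on the way to extravillous trophoblast, the invasive cells of the placenta. Estimated counts per library, in units of 1e+06, totalled 13.51 and 14.03 in WT EPSC, 13.92 and 12.06 in TP53KO EPSC, 12.33 and 12.44 in WT D7 and 12.10 and 12.42 in TP53KO D7. Whole reads recovered from the authors' normalised counts came, in the same unit, to 11.68 and 14.32 in WT EVT D3, 12.37 and 12.41 in TP53KO EVT D3, 11.51 and 12.15 in WT EVT D6 and 12.38 and 12.50 in TP53KO EVT D6. WT TSC values are TPM (transcripts scaled to a fixed total), whose depth is unknown. Levels below are means ± SD of 2 libraries in CPM (counts per 1e+06 counts) for EPSC and D7 and in normalised counts for EVT, and changes are log2 of TP53KO over WT ± SE (n = 2 against 2) unless another pair is named. Counting intervals and bounds cover counting error only. For a list that camera called, the counts adjusted over the list alone were the same as those over all genes where none are given.

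TP53 (ENSG00000141510; chromosome 17, 7661779 to 7687550, GRCh38) was lower in every TP53KO library than in every WT library of its stage. Estimated counts were 1770 and 1542 in WT EPSC against 83 and 74 in TP53KO EPSC (log2 change -4.32 ± 0.17, edgeR adjusted p = 2.55e-12). They were 343 and 341 in WT D7 against 28 and 42 in TP53KO D7 (-3.35 ± 0.19, edgeR adjusted p = 1.25e-10). Normalised counts were 521 and 577 in WT EVT D3 against 48.2 and 49.1 in TP53KO EVT D3 (-3.47 ± 0.16, limma adjusted p = 1.63e-44). At EVT D6 they were 522 and 587 in WT against 37.2 and 41.5 in TP53KO (-3.78 ± 0.16, limma adjusted p = 4.83e-60). WT TSC held 35.0 and 32.1 TPM.

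**Figure D1:**
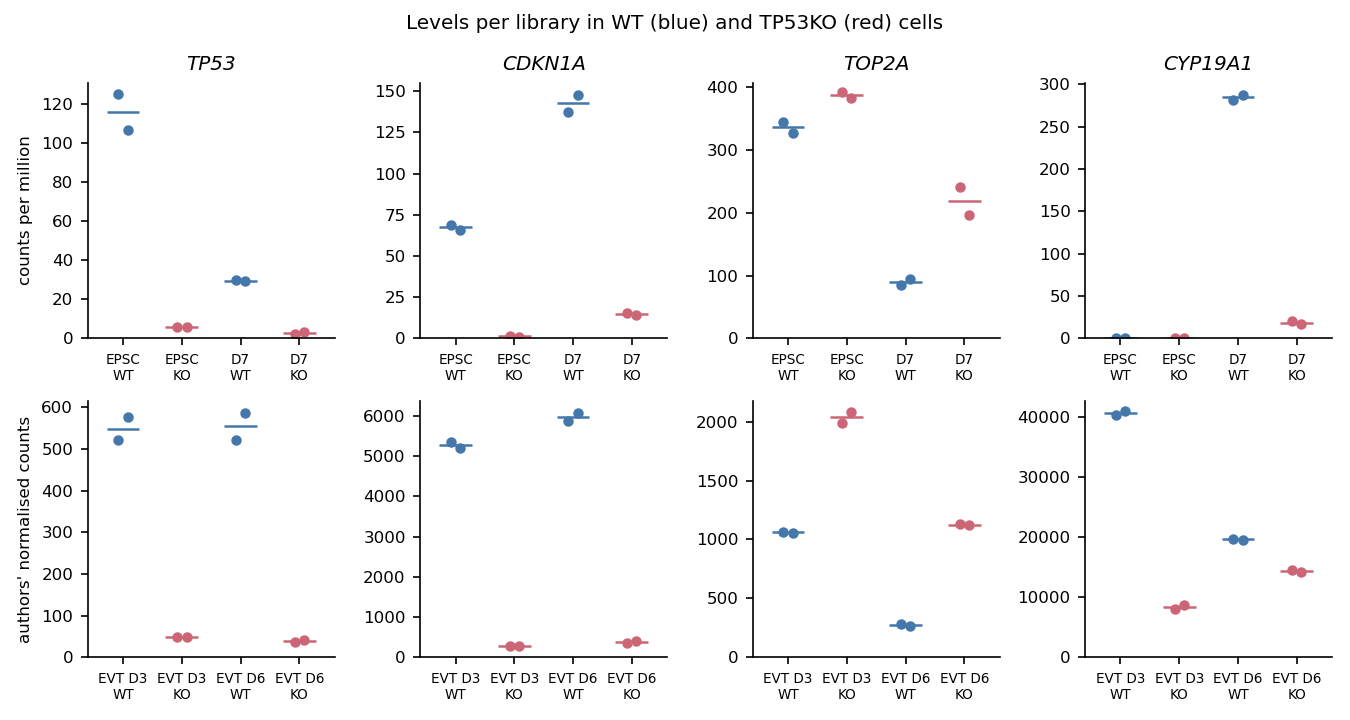
TP53, CDKN1A, TOP2A and CYP19A1 in each library, as CPM for EPSC and D7 (top) and as the authors' normalised counts for EVT D3 and EVT D6 (bottom); dots are libraries, lines are means of 2, blue is WT and red is TP53KO. TP53 and CDKN1A were lower in TP53KO at all stages drawn, and TOP2A was higher in TP53KO at D7, EVT D3 and EVT D6.

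The comparison of TP53KO with WT EPSC asked how cells without TP53 differed before differentiation. Chromosome 12 genes were also higher in the TP53KO cells of EPSC and D7, as given below. An effect of that rise on genes elsewhere was not separated from loss of TP53 at either stage. Of 40 listed TP53 targets, genes that the TP53 protein is known to switch on, 28 fell, 0 rose and 12 did not pass the test (32 fell and 1 rose adjusted over the list alone). CDKN1A (ENSG00000124762; chromosome 6, 36676460 to 36687339), an inhibitor of the cell cycle, fell from 67.5 ± 2.07 to 1.21 ± 0.03 CPM (log2 change -5.78 ± 0.19, edgeR adjusted p = 1.35e-13). GDF15, a secreted stress factor, fell by 4.83 ± 0.27 on the log2 scale, and TNFRSF10B, a death receptor, fell by 2.96 ± 0.15. The list's median was -1.24, or -1.21 with members at 0 counts in a group set to their bound (camera adjusted p = 1.32e-29, adjusted p = 0.00398 with an estimated correlation). Among the largest falls beside TP53, CDKN1A and GDF15 were the noncoding transcripts MIR34AHG and PURPL and the receptor gene EDA2R. MIR34AHG had 3 counts in TP53KO and 326 in WT, a ratio of 103 with an exact 95% counting interval of 35.0 to 503. PURPL fell by 4.34 ± 0.42 and EDA2R fell by 4.06 ± 0.43.

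The largest rises in TP53KO EPSC were ZNF729, ZNF257, ZNF676, ZNF208 and ZNF98, zinc finger genes of a cluster on chromosome 19, and the maternally expressed noncoding RNA MEG3. ZNF729 (ENSG00000196350; chromosome 19, 22286408 to 22317176) rose from 0.21 to 12.6 ± 1.53 CPM (log2 change 5.84 ± 0.49, edgeR adjusted p = 6.2e-07). ZNF676 rose by 3.88 ± 0.32, ZNF208 by 3.86 ± 0.34, ZNF98 by 3.79 ± 0.42 and ZNF257 from 0.634 ± 0.505 to 10.3 ± 3.11 CPM, and reads of these similar genes are uncertain because they can be assigned to a relative. MEG3 (ENSG00000214548; chromosome 14, 100779410 to 100861031) rose from 3.68 ± 0.60 to 45.9 ± 1.83 CPM (3.64 ± 0.23). It belongs to the imprinted placental genes, of which 4 of 18 rose and 2 fell (9 and 2 adjusted over the list alone). CDKN1C, an imprinted growth inhibitor, fell by 1.39 ± 0.13 and KCNQ1OT1, a noncoding RNA of the same region, rose by 0.89 ± 0.14. The list's median was 0.33 (camera adjusted p = 0.00634, adjusted p = 0.412 with an estimated correlation), and 0.52 without WT replicate 1.

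Stress and signalling lists were also called in EPSC. Of 19 ATF4 and unfolded protein response genes 9 rose and 2 fell (11 and 4 adjusted over the list alone), among them TRIB3, a pseudokinase (1.04 ± 0.14), and SLC7A11, a cystine transporter (0.88 ± 0.13). SHMT2 (0.86 ± 0.11), a serine pathway enzyme, lies on chromosome 12. Of 16 WNT targets 4 rose and 0 fell (5 and 0 adjusted over the list alone), including BMP4 (0.95 ± 0.15) and RNF43 (0.98 ± 0.23). Of 18 BMP and TGF-beta targets 0 rose and 3 fell (1 and 3 adjusted over the list alone), including LEFTY1, a NODAL inhibitor (-1.03 ± 0.13), ID3 (-0.77 ± 0.15) and SERPINE1, a protease inhibitor (-1.83 ± 0.22). Of 13 naive pluripotency genes 2 rose and 0 fell (6 and 0 adjusted over the list alone), NLRP7 by 1.11 ± 0.16 and KLF5 by 0.92 ± 0.21. Of 24 ribosomal protein genes 3 fell and 0 rose (8 and 0 adjusted over the list alone), RPL3 by -0.40 ± 0.10. Medians were 0.38 for ATF4 genes, 0.36 for WNT targets, -0.26 for BMP and TGF-beta targets, 0.35 for naive pluripotency and -0.20 for ribosomal proteins. Camera adjusted p was 0.00927, 0.00634, 0.0342, 0.0395 and 0.000822 for these in turn, and with an estimated correlation the adjusted p was 0.48, 0.412, 0.412, 0.412 and 0.721. WT EPSC replicate 2 lay above WT EPSC replicate 1 by a median of 0.27 in ribosomal protein genes, 0.19 in BMP and TGF-beta targets and 0.15 in ATF4 genes, and below it by a median of -0.23 in WNT targets.

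The other 17 lists did not pass the camera test in EPSC. Of 25 G2/M and mitosis genes 2 rose and 0 fell, FOXM1, a mitotic transcription factor on chromosome 12 (0.84 ± 0.13), and MKI67, a proliferation antigen (0.68 ± 0.16). Of 25 G1/S and replication genes 2 fell, PCNA (-0.55 ± 0.12) and GINS2 (-0.57 ± 0.15), and 0 rose. Of 15 YAP targets 3 fell and 1 rose, and CCN1 (-1.13 ± 0.11), AJUBA (-1.01 ± 0.13) and CCN2 (-0.57 ± 0.12) were those that fell. Adjusted over the list alone, 2 G2/M genes rose, 4 G1/S genes fell, and 2 YAP targets rose and 4 fell. Single genes of other lists also passed the test, among them ADM, a vasoactive peptide of the hypoxia list (-1.42 ± 0.15), COL1A1, a collagen (-0.88 ± 0.13), KRT19, an epithelial keratin (-0.47 ± 0.11), PGF, a placental growth factor (-1.08 ± 0.23), and FN1, fibronectin (0.76 ± 0.13). Of the genes named in EPSC, CCN2, FN1, GINS2, ID3, KLF5, KRT19, MDM2, MKI67, PCNA, PGF, RNF43 and RPL3 did not pass the test under at least 1 other setting. Median, mean and camera direction differed in sign for apoptosis machinery, primed pluripotency, extravillous trophoblast, mesenchyme and EMT, YAP targets, hypoxia and glycolysis and interferon response.

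Of 17393 genes tested in EPSC, 635 rose and 418 fell (edgeR quasi-likelihood test, adjusted p of 0.05). Chromosome 12 held 245 of the rises and 3 of the falls. The median log2 change of its 932 tested genes was 0.43, against -0.11 to 0.06 for other autosomes (camera adjusted p = 1.88e-23, adjusted p = 0.000963 with an estimated correlation), and without its genes 345 rose and 301 fell. Camera also called chromosome 19 as lower (17 rose and 65 fell of 1299 genes, median -0.11, camera adjusted p = 0.0146, adjusted p = 0.751 with an estimated correlation). Total calls were 4500 without WT replicate 1, 170 without TP53KO replicate 1, 307 without TP53KO replicate 2 and 202 when the EPSC libraries were fitted alone, so the count rests on single libraries. The ribosomal protein call ended without WT replicate 2 (median -0.04, camera adjusted p = 0.21). The BMP and TGF-beta call ended without WT replicate 2 or TP53KO replicate 2 (camera adjusted p = 0.21 and 0.0846). The WNT median was 0.19 and the naive pluripotency median 0.21 without TP53KO replicate 1. The ATF4 call ended without WT replicate 1 (adjusted p = 0.52) and the naive pluripotency call when any of the 4 libraries was left out (adjusted p = 0.0625 to 0.52).

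The comparison of WT D7 with WT EPSC asked what 7 days of differentiation changed with TP53 present, and gives the background for the knockout at D7. Changes here are log2 of D7 over EPSC. Pluripotency genes were lower and trophoblast genes higher: 23 of 24 primed pluripotency genes fell and 0 rose, 26 of 26 syncytiotrophoblast genes rose, and 26 of 28 trophectoderm and cytotrophoblast genes rose and 2 fell. POU5F1, a pluripotency factor, fell from 1893 ± 42.7 to 1.30 ± 0.72 CPM (-10.50 ± 0.21, edgeR adjusted p = 2.32e-18). TDGF1, SOX2 and PRDM14 were the largest falls, each with 0 counts in WT D7 and at least 3816-fold, 2752-fold and 1748-fold lower against a floor of 3 counts over the group. P2RY6, the amnion-list gene VTCN1 and PRR9 were the largest rises, each with 0 counts in WT EPSC and at least 4162-fold, 3970-fold and 2720-fold higher on the same floor. HAND1, an early trophoblast and amnion factor, rose by 12.45 ± 0.25, MSX2 by 9.61 ± 0.19, TBX3 by 8.97 ± 0.21 and PGF by 6.80 ± 0.17. COL3A1, a collagen, rose by 13.21 ± 0.23, PAPPA2 by 8.64 ± 0.21, CDKN1C by 4.65 ± 0.14 and the glucose transporter SLC2A1 by 3.61 ± 0.11. Medians were -7.09 for primed pluripotency, 8.90 for syncytiotrophoblast (6.90 with members at 0 counts set to their bound) and 6.88 for trophectoderm and cytotrophoblast (5.78 likewise).

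Proliferation genes were lower in WT D7: 25 of 25 G2/M and mitosis genes fell (median -2.22), as did 22 of 25 G1/S and replication genes (median -2.13) while 1 rose. BUB1, a mitotic kinase, fell by 3.49 ± 0.14 and MCM6, a replication helicase subunit, by 3.24 ± 0.13. Of 22 epithelial junction genes 19 rose and 1 fell, among them CLDN4 (7.67 ± 0.17) and DSP (5.66 ± 0.14). Camera called 12 lists, and 6 of the calls held with an estimated correlation: syncytiotrophoblast, primed pluripotency and G2/M (adjusted p = 0.015 each), trophectoderm and cytotrophoblast and G1/S (0.0194 each) and epithelial junctions (0.0214). The amnion list, with 13 of 14 genes higher, had camera adjusted p = 5.26e-07 and adjusted p = 0.0928 with an estimated correlation. Mesenchyme and EMT (13 of 19 rose), WNT targets (12 of 16), YAP targets (12 of 15), imprinted placental genes (13 of 18) and extravillous trophoblast (16 of 27) were also called as higher, with adjusted p = 0.113, 0.197, 0.316, 0.141 and 0.28 with an estimated correlation. Counts adjusted over the list alone were the same for every list named in this comparison. TP53 itself fell by 1.97 ± 0.14, and of 40 TP53 targets 19 rose and 12 fell. For naive pluripotency the median was 0.92 and the mean -1.91, with 6 rises and 6 falls. In all 6325 genes rose and 6158 fell of 17393 (edgeR adjusted p of 0.05).

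The comparison of TP53KO with WT D7 asked how cells without TP53 differed after differentiation, with the same limit from chromosome 12 as in EPSC. Syncytiotrophoblast genes, those of the fused hormone-making layer of the placenta, were lower: 22 of 26 fell, 0 rose and 4 did not pass the test, with a median of -3.55 (camera adjusted p = 3.51e-15, adjusted p = 0.00774 with an estimated correlation). CGA (ENSG00000135346; chromosome 6, 87085498 to 87095406), the shared subunit of placental and pituitary hormones, fell from 277 ± 5.89 to 11 ± 1.66 CPM (-4.66 ± 0.15, edgeR adjusted p = 4.75e-13). CYP19A1 (ENSG00000137869; chromosome 15, 51208057 to 51338610), the aromatase, fell from 285 ± 4.41 to 18.6 ± 2.23 CPM (-3.93 ± 0.15) and PGF from 472 ± 8.60 to 43.9 ± 4.55 CPM (-3.43 ± 0.13). Of 28 trophectoderm and cytotrophoblast genes 14 fell and 1 rose (16 and 1 adjusted over the list alone), with falls in the keratin KRT23 (-2.89 ± 0.13), the transcription factor GATA2 (-1.64 ± 0.14) and the keratin KRT7 (-1.40 ± 0.12). Of 27 extravillous trophoblast genes 12 fell and 4 rose (15 and 4 adjusted over the list alone), with falls in NOTUM, a WNT inhibitor (-1.77 ± 0.17), FN1 (-1.56 ± 0.13) and PAPPA2, a protease (-1.19 ± 0.12). The medians of these lists were -0.42 and -0.75 (camera adjusted p = 4.53e-05 and 0.00501, adjusted p = 0.1 and 0.204 with an estimated correlation).

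G2/M and mitosis genes were higher in TP53KO D7: 25 of 25 rose, with a median of 0.85 (camera adjusted p = 6.24e-14, adjusted p = 0.00774 with an estimated correlation). TPX2, a spindle factor, rose from 95.9 ± 4.32 to 254 ± 8.81 CPM (1.41 ± 0.11, edgeR adjusted p = 7.45e-09), TOP2A by 1.28 ± 0.12 and KIF20A by 1.30 ± 0.13. Of 25 G1/S and replication genes 9 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.20, camera adjusted p = 0.0415, adjusted p = 0.195 with an estimated correlation). MCM3 (0.57 ± 0.11) and MCM6 (0.63 ± 0.12) rose, and the 1 that fell was CCNE1, a cyclin of the G1/S step (-1.35 ± 0.13). TP53 targets were again lower: 30 of 40 fell and 1 rose, with a median of -1.10 (camera adjusted p = 2.26e-13, adjusted p = 0.00774 with an estimated correlation). CDKN1A fell from 143 ± 7.32 to 15.1 ± 0.81 CPM (-3.24 ± 0.14) and GDF15 by 4.44 ± 0.20. All 13 mitochondrial transcripts fell (median -1.15, camera adjusted p = 1.45e-09, adjusted p = 0.195 with an estimated correlation).

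The largest rises at D7 were MEG3, H19, ZNF676, ZNF208, ZNF681 and RGPD2. H19 (ENSG00000130600; chromosome 11, 1995176 to 2001470), an imprinted noncoding RNA, rose from 10.4 ± 1.08 to 415 ± 29.7 CPM (5.31 ± 0.17, edgeR adjusted p = 6.24e-14) and MEG3 by 6.70 ± 0.41. ZNF676 had 0 counts in WT and was at least 88.9-fold higher. ZNF208 rose by 5.33 ± 0.55, ZNF681 by 5.16 ± 0.65 and RGPD2 by 5.23 ± 0.35, and all 4 of these genes have near copies, so their counts are uncertain. Imprinted genes moved both ways, 6 of 18 up and 5 down (6 and 6 adjusted over the list alone; camera adjusted p = 0.84), with falls in PHLDA2, a placental growth regulator (-4.40 ± 0.15), and CDKN1C (-3.61 ± 0.13). The largest falls were LINC00678, INPP5D, HSD11B2, MRGPRX1, SERPINB7 and TWIST2. INPP5D (ENSG00000168918; chromosome 2, 233059967 to 233207903), a lipid phosphatase, had 1 count in TP53KO and 607 in WT, a ratio of 635 (exact 95% counting interval 114 to 25133). SERPINB7 had 1 against 144 counts (151, interval 26.6 to 5993) and TWIST2, a mesenchymal factor, 2 against 206 (108, interval 29.5 to 896). LINC00678 had 0 counts in TP53KO and was at least 43.6-fold lower. HSD11B2, the placental cortisol-inactivating enzyme, fell by 7.09 ± 0.39. MRGPRX1 fell by 6.96 ± 0.53, though MRGPRX1 did not pass in DESeq2 (adjusted p = 0.291).

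Lists near the threshold at D7 were primitive streak and mesoderm (2 of 8 rose, 0 fell, median 0.67), primed pluripotency (9 of 24 rose, 3 fell, median 0.45, or 0.40 at the bound), ribosomal proteins (4 of 24 rose, 0 fell, median 0.20) and epithelial junctions (4 of 22 rose, 11 fell, median -0.33), each with camera adjusted p = 0.0497. Adjusted over the list alone, 2, 11, 3 and 4 of these rose and 0, 3, 0 and 13 fell. With an estimated correlation their adjusted p was 0.204, 0.195, 0.877 and 0.195. Among their members POU5F1 rose from 1.30 ± 0.72 to 5.18 ± 0.74 CPM (1.99 ± 0.27), SALL4 rose by 0.80 ± 0.11, SFRP2, a WNT modulator, fell by 3.46 ± 0.12, HAND2 rose by 2.61 ± 0.24, EPCAM rose by 0.92 ± 0.13 and CLDN3 fell by 0.99 ± 0.14. RPS14 rose by 0.45 ± 0.12, which edgeR did not call without WT replicate 2 or TP53KO replicate 1. The lists of naive pluripotency (1 rose and 4 fell of 13), ATF4 and unfolded protein response (4 and 10 of 19), interferon response (1 and 4 of 12), apoptosis machinery (2 and 3 of 21) and amnion (4 and 6 of 14) did not pass the camera test. Nor did endoderm (3 and 2 of 12), neuroectoderm (2 and 1 of 9), mesenchyme and EMT (6 and 5 of 19), WNT targets (5 and 3 of 16), BMP and TGF-beta targets (4 and 5 of 18), YAP targets (3 and 2 of 15) and hypoxia and glycolysis (9 and 5 of 24). Adjusted over the list alone these counts were the same, except for endoderm (3 and 3), mesenchyme and EMT (8 and 6), YAP targets (4 and 2) and hypoxia and glycolysis (9 and 6). Members with the smallest adjusted p included KLF4 (-2.25 ± 0.16), ATF3 (-1.53 ± 0.13), CEBPB (403 ± 10.3 to 176 ± 4.92 CPM), EGLN3, an oxygen sensor (-2.83 ± 0.17), IFI6 (-1.78 ± 0.17), and BCL2L1, a survival factor (-1.02 ± 0.11). Others were VTCN1 (-0.80 ± 0.12), NES (1.43 ± 0.12), LUM on chromosome 12 (183 ± 6.73 to 420 ± 35.8 CPM) and SLC2A3, a glucose transporter on chromosome 12 (0.78 ± 0.10). Median, mean and camera direction differed in sign for apoptosis machinery, mesenchyme and EMT, WNT, BMP and TGF-beta and YAP targets.

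Of 17393 genes tested at D7, 2304 rose and 2528 fell (edgeR adjusted p of 0.05), and chromosome 12 held 401 of the rises and 40 of the falls. The median of its 932 genes was 0.58, against -0.14 to 0.08 for other autosomes (camera adjusted p = 2.68e-16, adjusted p = 0.002 with an estimated correlation). Total calls were 2722 without WT replicate 1, 2883 without WT replicate 2 and 2615 without TP53KO replicate 1. The calls on G1/S, primed pluripotency, primitive streak and mesoderm, epithelial junctions and ribosomal proteins ended without at least 1 of the 4 D7 libraries (camera adjusted p = 0.0536 to 0.23 there), and without chromosome 12 genes primed pluripotency was no longer called (adjusted p = 0.0774) and ATF4 and unfolded protein response was, as lower (adjusted p = 0.0288).

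The difference between the TP53KO effects at D7 and in EPSC was tested directly, to ask whether TP53KO cells departed from WT differently before and after differentiation. The G2/M effect was higher at D7: 22 of 25 genes differed upward and 0 downward (median 0.89, camera adjusted p = 2.01e-13, adjusted p = 0.0125 with an estimated correlation), BUB1 by 1.29 ± 0.18 and TPX2 by 1.16 ± 0.15. The syncytiotrophoblast effect was lower at D7: 9 of 26 genes differed downward and 0 upward (median -2.47, camera adjusted p = 1.2e-16, adjusted p = 0.0125 with an estimated correlation), HSD11B2 by -6.85 ± 0.49, PGF by -2.34 ± 0.28 and SDC1, a syndecan, by -2.24 ± 0.19. Of the 26 genes 14 had 0 counts in an EPSC group, where no effect could be measured, so for these the difference restates the fall at D7. The fall of CDKN1A was smaller at D7 than in EPSC by 2.54 ± 0.25, that of TP53 by 0.97 ± 0.27, and 10 of 40 TP53 targets differed upward and 3 downward (11 and 4 adjusted over the list alone; median 0.35, camera adjusted p = 0.199). PHLDA2 (-3.51 ± 0.21), CDKN1C (-2.23 ± 0.18), SFRP2 (-3.46 ± 0.16), KLF4 (-2.68 ± 0.22), FN1 (-2.33 ± 0.19), FLT1 (-1.86 ± 0.22), KRT7 (-1.68 ± 0.22), EGLN3 (-2.72 ± 0.22), ATF3 (-1.91 ± 0.20) and CEBPB (-1.67 ± 0.18) differed downward, and NES (1.97 ± 0.16) and POU5F1 (2.05 ± 0.30) upward. INPP5D was among the largest downward differences (-7.65 ± 0.67), a fitted value that rests on 1 count in TP53KO D7.

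Camera also called mitochondrial transcripts (13 of 13 lower, median -1.29), trophectoderm and cytotrophoblast (7 of 28 lower, median -0.61), ribosomal proteins (7 of 24 higher, median 0.41), and ATF4 and unfolded protein response (8 of 19 lower and 2 higher, median -0.44). Further calls were G1/S (5 of 25 higher and 1 lower, median 0.31), naive pluripotency (6 of 13 lower, median -1.14) and extravillous trophoblast (9 of 27 lower and 1 higher, median -0.41). Adjusted over the list alone, 9 trophectoderm and cytotrophoblast genes were lower and 1 higher, 13 ribosomal protein genes were higher, 10 ATF4 genes were lower and 2 higher, 7 G1/S genes were higher and 1 lower, and 11 extravillous trophoblast genes were lower and 2 higher. Their camera adjusted p in turn was 2.21e-11, 4.5e-06, 6.42e-05, 0.000741, 0.00225, 0.00393 and 0.00883, and with an estimated correlation it was 0.125, 0.092, 0.46, 0.256, 0.115, 0.125 and 0.256. Of 17393 genes, 862 differed upward and 1204 downward (edgeR adjusted p of 0.05). Leaving out single libraries moved the total between 1086 without TP53KO EPSC replicate 1 and 4570 without WT EPSC replicate 1, and it lay between 1099 and 1183 without TP53KO EPSC replicate 2, TP53KO D7 replicate 1 or either WT D7 library. The TP53 difference did not pass in edgeR without either TP53KO EPSC library, either WT D7 library or TP53KO D7 replicate 2.

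**Figure D2:**
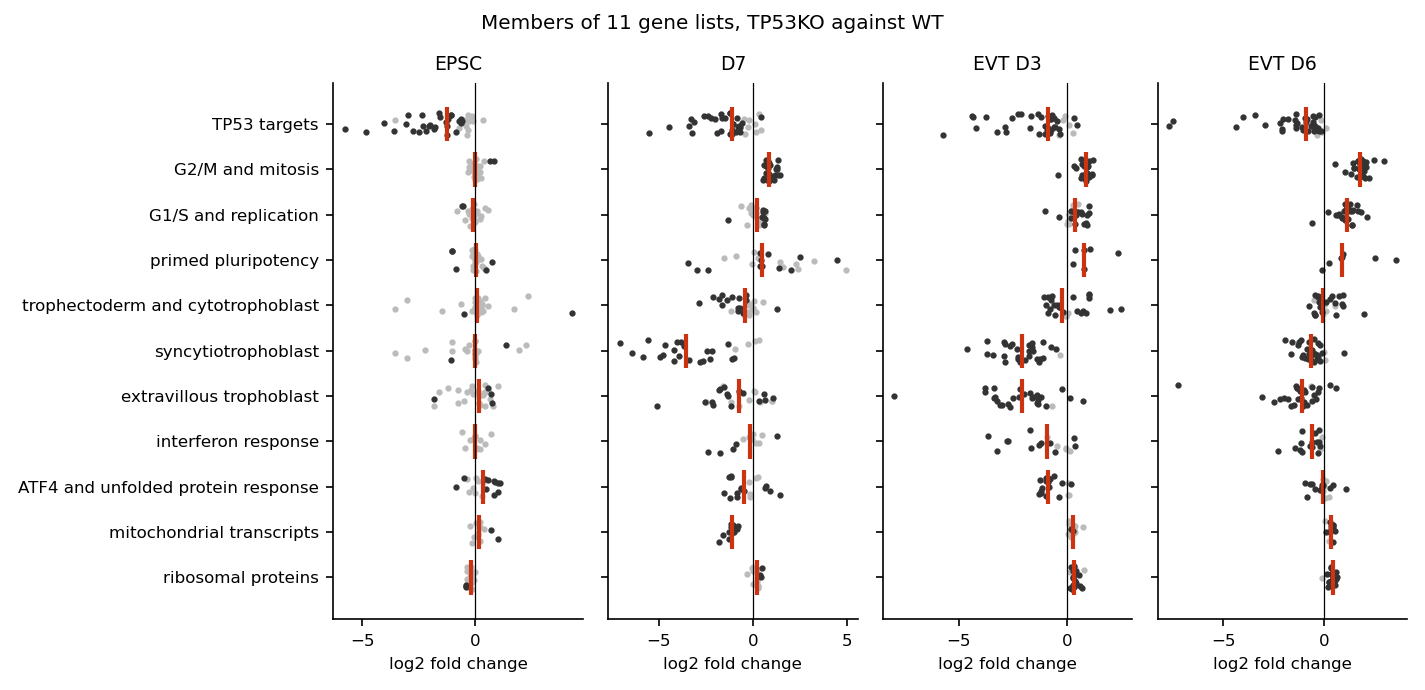
Log2 change, TP53KO over WT, of each measured member of 11 gene lists in EPSC, D7, EVT D3 and EVT D6; black dots passed an adjusted p of 0.05, grey dots did not, and red bars are medians. TP53 targets lay mostly below 0 in all 4 panels, and the G2/M median was 0.01 in EPSC, 0.85 at D7, 0.88 at EVT D3 and 1.78 at EVT D6.

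The comparison of TP53KO with WT EVT D3 asked what loss of TP53 changed 3 days into the formation of extravillous trophoblast. Extravillous trophoblast genes were lower: 25 of 28 fell and 2 rose (26 and 2 adjusted over the list alone), with a median of -2.07. FLT1 (ENSG00000102755; chromosome 13, 28300344 to 28495145), a receptor for vascular growth factors, fell from 5713 ± 39.5 to 563 ± 28.5 normalised counts (-3.34 ± 0.05, limma adjusted p = 4.8e-95), and ADAM12 (-3.07 ± 0.05) and ADAM19 (-2.48 ± 0.04), membrane proteases, fell too. HLA-G, the class I gene of these cells, chosen after its values were seen, fell from 1197 to 620 normalised counts (-0.95). Syncytiotrophoblast genes were lower as well, 29 of 30 (median -2.05). The chorionic gonadotropin genes CGB3, CGB5 and CGB8 fell by 2.84 to 2.89, and since they are near-identical copies their separate values are uncertain. Camera adjusted p was 1.27e-11 for the extravillous and 5.52e-15 for the syncytiotrophoblast list, and adjusted p = 0.176 and 0.211 with an estimated correlation.

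TP53 targets fell in 32 of 39 cases and 2 rose (33 and 2 adjusted over the list alone; median -0.88), including CDKN1A (5285 ± 105 to 287 ± 3.44 normalised counts, -4.20 ± 0.06), GDF15 (-4.34 ± 0.07) and PGF (-1.27 ± 0.04). G2/M and mitosis genes rose in 24 of 25 cases and 1 fell (median 0.88), including TOP2A (0.94 ± 0.06), MKI67 (0.90 ± 0.06) and CENPF (0.94 ± 0.08). G1/S genes rose in 15 of 25 cases and 2 fell (16 and 2 adjusted over the list alone; median 0.37), MCM3 rising by 1.02 ± 0.05 and CCNE1 falling by 0.99 ± 0.04. Of 24 ribosomal protein genes 21 rose and 0 fell (median 0.32), RPL15 by 0.57 ± 0.04. Only 6 of 24 listed primed pluripotency genes passed the level filter, and all 6 rose (median 0.81), among them the DNA methyltransferase DNMT3B (1.08 ± 0.06) and SALL4 (0.81 ± 0.08). Of 10 naive pluripotency genes 8 fell and 1 rose (median -1.41), among them KLF4 (-1.14 ± 0.05) and SUSD2 (-2.37 ± 0.09). Of 19 ATF4 and unfolded protein response genes 15 fell and 1 rose (median -0.87), among them the chaperone HSPA5 (-0.88 ± 0.03) and CEBPB (-1.18 ± 0.04). Of 17 interferon response genes 10 fell and 2 rose (median -0.93), among them MX1 (-1.30 ± 0.06), IFIT1 (-1.67 ± 0.10) and IFIT3 (-3.24 ± 0.19). Of 21 hypoxia and glycolysis genes 13 fell and 4 rose (median -0.32), among them ADM (-2.41 ± 0.06) and the glucose transporter SLC2A1 (-1.02 ± 0.03). Camera adjusted p for these lists in turn was 2.86e-09, 7.04e-08, 0.00135, 2.83e-05, 0.00237, 0.00472, 0.000192, 0.002 and 0.0139. With an estimated correlation it was 0.176, 0.176, 0.236, 0.49, 0.236, 0.25, 0.211, 0.236 and 0.518, so no list call at EVT D3 held there. The estimated correlation was -0.033 for extravillous trophoblast, -0.019 for TP53 targets and -0.012 for G2/M, below the preset 0.01. It was higher for others, such as ribosomal proteins (0.32). For lists below the preset the loss does not show that correlation between genes undid the call.

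The largest falls at EVT D3 were PAPPA, PURPL, SPATA18, SPDYE8, MIR34AHG and KCNJ2. PAPPA, a protease secreted by trophoblast, had 0 reads in TP53KO and was at least 181-fold lower, PURPL at least 96.4-fold lower, and SPATA18, a mitochondrial quality gene, had 3 against 194 reads (ratio 74.3, exact 95% counting interval 25 to 363). SPDYE8, whose counts are uncertain because of near copies, had 1 against 136 reads (156, interval 27.6 to 6213), MIR34AHG fell by 5.11 ± 0.49 and the potassium channel gene KCNJ2 fell by 4.72 ± 0.11. The largest rises were the pseudogenes NOC2LP1 (at least 57.5-fold, 0 reads in WT) and KRT8P37 (1 against 128 reads, ratio 112, interval 19.7 to 4437), both uncertain as copies of other genes, LINC02693 (4.24 ± 0.40), the matrix gene HAPLN1 (4.14 ± 0.47), the actin regulator EVL (3.63 ± 0.20) and CRYZL2P (3.61 ± 0.47). Lists past no camera test held members moving both ways: trophectoderm and cytotrophoblast (10 rose and 15 fell of 28, median -0.23 and mean 0.06), epithelial junctions (11 and 9 of 22), imprinted placental genes (5 and 4 of 14), BMP and TGF-beta targets (3 and 6 of 13), and mesenchyme and EMT (2 and 5 of 9). The same held for WNT targets (4 and 2 of 8), YAP targets (5 and 3 of 13), apoptosis machinery (7 and 4 of 21), amnion (4 and 2 of 7) and endoderm (1 and 3 of 6). Mitochondrial transcripts (2 rose and 0 fell of 13) did not pass either. Primitive streak and mesoderm and neuroectoderm had too few measured members to test. Within these lists EGFR (-1.04 ± 0.03), KRT18 (-0.86 ± 0.03), SPARC (-2.16 ± 0.12), SERPINE1 (-1.59 ± 0.03), CDKN1C (-0.87 ± 0.03) and the survival factor BCL2 (-2.29 ± 0.13) fell, and EPCAM (1.32 ± 0.05), CLDN3 (1.24 ± 0.05), CLDN6 (0.90 ± 0.04) and the imprinted PEG10 (0.77 ± 0.03) rose.

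Of 13909 genes tested at EVT D3, 3712 rose and 4203 fell (limma adjusted p of 0.05), and 46.9% of calls were rises. Scaling each library to its total in place of the authors' factors shifted the median of all genes from 0.02 to 0.29 and made 71.0% of calls rises, so directions of small changes are relative to the scaling. Quantile normalisation ended the hypoxia and glycolysis call (camera adjusted p = 0.102) and called epithelial junctions (0.00465) and mitochondrial transcripts (0.00387) as higher. Chromosome 12 had a median of 0.04 over 702 genes, with 207 rises and 201 falls (camera adjusted p = 0.896).

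The comparison of TP53KO with WT EVT D6 asked the same at 6 days. Extravillous trophoblast genes were lower, 25 of 28 falling and 2 rising (median -1.11). HTRA4 (ENSG00000169495; chromosome 8, 38974164 to 38988662), a secreted protease, fell from 37577 ± 478 to 9360 ± 92.7 normalised counts (-2.01 ± 0.02, limma adjusted p = 1.61e-176), NOTUM by 2.47 ± 0.03 and FN1 by 1.40 ± 0.02. HLA-G, chosen after its values were seen, fell from 6102 to 4038 normalised counts (-0.60). Syncytiotrophoblast genes fell in 27 of 30 cases and 1 rose (median -0.64), among them SDC1 (-1.07 ± 0.02), TFPI (-1.23 ± 0.03) and PSG3 (-1.60 ± 0.02), the last of a family of near copies and so uncertain. TP53 targets fell in 34 of 39 cases and 0 rose (35 and 0 adjusted over the list alone; median -0.92), with CDKN1A at 5976 ± 145 in WT and 369 ± 35.8 normalised counts in TP53KO (-4.02 ± 0.05), GDF15 (-3.42 ± 0.05) and PLK2 (-1.11 ± 0.03). All 25 G2/M and mitosis genes rose (median 1.78), TOP2A by 2.03 ± 0.08, MKI67 by 1.91 ± 0.08 and CENPF by 1.88 ± 0.12, and 23 of 24 G1/S genes rose while CCNE1 fell by 0.61 ± 0.03 (median 1.14), MCM3 rising by 1.26 ± 0.06 and RRM2 by 1.65 ± 0.09. Interferon response genes fell in 15 of 17 cases and 0 rose (median -0.60), IFIT2 by 2.29 ± 0.04, IFIT1 by 1.21 ± 0.03 and IFIT3 by 1.44 ± 0.04. Camera adjusted p for these 6 lists in turn was 2.11e-11, 1.02e-09, 3.46e-14, 1.67e-13, 1.47e-09 and 6.3e-07, and adjusted p = 0.204 for each with an estimated correlation.

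Other lists called at EVT D6 were ribosomal proteins (22 of 24 rose, median 0.40, with RPL8 at 0.56 ± 0.03), mitochondrial transcripts (10 of 13 rose, median 0.33) and WNT targets (4 of 8 rose, median 0.68). Primed pluripotency (7 of 24 listed genes measured, of which 6 rose and 1 fell, median 0.87, with DNMT3B at 0.82 ± 0.09 and SALL4 at 0.87 ± 0.12) and epithelial junctions (13 of 22 rose and 5 fell, median 0.19) were called too. Camera adjusted p in turn was 3.29e-06, 0.00127, 0.0067, 0.00854 and 0.0149, and with an estimated correlation 0.275, 0.419, 0.302, 0.275 and 0.419. The junction genes EPCAM (1.87 ± 0.07), CLDN3 (1.83 ± 0.06) and CLDN6 (1.34 ± 0.05) rose. Lists that did not pass were trophectoderm and cytotrophoblast (10 rose and 12 fell of 27), imprinted placental genes (6 and 4 of 14), hypoxia and glycolysis (8 and 8 of 22), ATF4 and unfolded protein response (3 and 10 of 19), and naive pluripotency (2 and 4 of 10). Nor did BMP and TGF-beta targets (3 and 7 of 14), YAP targets (8 and 3 of 14), mesenchyme and EMT (2 and 4 of 9), apoptosis machinery (7 and 6 of 21), amnion (2 and 3 of 9) or endoderm (2 and 1 of 8) pass. Within them the imprinted genes PEG3 (1.31 ± 0.03), IGF2 (0.78 ± 0.02) and PEG10 (0.86 ± 0.02), LDHA (1.27 ± 0.06) and SLC7A11 (1.07 ± 0.07) rose, and SPARC (-2.10 ± 0.04), ADM (-1.63 ± 0.04), SERPINE1 (-0.87 ± 0.02), KLF4 (-0.99 ± 0.04), SP6 (-0.74 ± 0.03) and GATA2 (-0.53 ± 0.02) fell. The largest falls were SPATA18 (0 reads in TP53KO, at least 144-fold), EDA2R (2 against 659 reads, ratio 369, exact 95% counting interval 102 to 3052), PAPPA (-7.22 ± 0.26), PURPL (at least 92.5-fold), the imprinting regulator ZFP57 (at least 77.2-fold) and MIR34AHG (2 against 267 reads, 149, interval 41.0 to 1240). The largest rises were NOC2LP1 (at least 39.3-fold, uncertain as a pseudogene), CRYZL2P (4.58 ± 0.58), LINC02693 (3.95 ± 0.46), LRATD1 (3.83 ± 0.30), NLRP2, a maternal-effect gene (3.32 ± 0.10), and the chemokine CXCL14 (3.28 ± 0.13). Of 14022 genes tested, 3316 rose and 3404 fell (limma adjusted p of 0.05), 49.3% of calls being rises against 61.9% with each library scaled to its total. Chromosome 12 had a median of -0.02 over 699 genes (camera adjusted p = 0.985). For trophectoderm and cytotrophoblast, hypoxia and glycolysis and endoderm, median, mean and camera direction differed in sign.

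**Figure D3:**
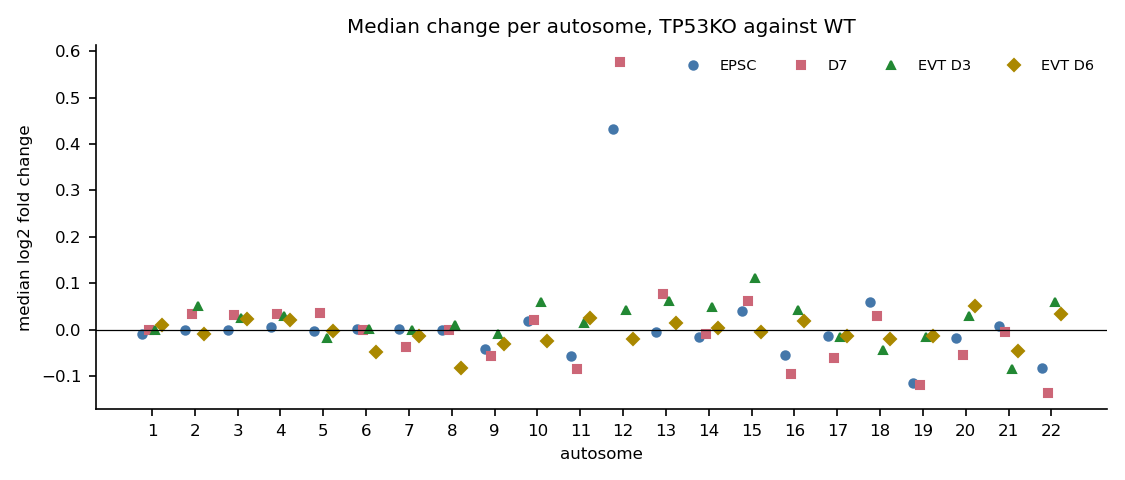
Median log2 change, TP53KO over WT, of the tested genes of each autosome from 1 to 22 in EPSC, D7, EVT D3 and EVT D6. Chromosome 12 stood at 0.43 in EPSC and 0.58 at D7, and at 0.04 and -0.02 at EVT D3 and EVT D6.

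The overlap of the 4 TP53KO comparisons asked which genes moved the same way at every stage measured. Of 13016 genes tested in all 4, 70 fell in each, where independent lists would share 4.46, and 61 rose in each, where they would share 5.04. The comparisons share no libraries, but EPSC and D7 are the same cells in a joint fit, and both EVT stages derive from TSC. Lists within these pairs are related, so the expected counts understate what such lists would share. Genes that fell in each included CDKN1A, MDM2 (-0.56 in EPSC, -0.72 at D7, -1.19 at EVT D3 and -1.39 at EVT D6), ZMAT3 (-1.82, -1.14, -0.75 and -1.04), RPS27L (-1.76, -1.68, -2.24 and -2.11), SERPINE1 (-1.83, -1.83, -1.59 and -0.87) and PGF (-1.08, -3.43, -1.27 and -0.82). Genes that rose in each included MKI67 (0.68, 0.87, 0.90 and 1.91), FOXM1 on chromosome 12 (0.84, 1.12, 0.68 and 1.82), BMP4 (0.95, 0.51, 0.90 and 0.77) and RNF43 (0.98, 0.85, 1.36 and 0.98). Of these, MDM2, PGF, MKI67 and RNF43 did not pass in EPSC under at least 1 other setting. The genes named here were chosen after their values were seen, and BMP4 did not pass in edgeR at D7 without WT replicate 1. EPSC and D7 shared 315 rises and 182 falls (84.1 and 60.8 for independent lists), EPSC and EVT D3 173 and 147 (151 and 107), and EPSC and EVT D6 150 and 132 (134 and 87.5). D7 and EVT D3 shared 769 and 1166 (489 and 677), D7 and EVT D6 590 and 812 (438 and 547), and EVT D3 and EVT D6 2121 and 2372 (884 and 998). Opposite changes also exceeded those of independent lists in some pairs: 206 EPSC rises fell at EVT D3 (163) and 179 at EVT D6 (132), 110 EPSC falls rose at EVT D6 (89.1), and 642 D7 falls rose at EVT D6 (557). Without chromosome 12 genes the 4 comparisons shared 29 rises and 58 falls, and 2 rises and 17 falls had a log2 change of at least 1 in each. The overlap was not run with the EPSC libraries fitted alone, where EPSC had 109 rises and 93 falls, or with a library left out. Its size under those settings is therefore unknown.

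WT TSC were described without a comparison, since no TP53KO column could be given to a sample. Of 40 TP53 targets 35 had a mean of at least 10 TPM, CDKN1A at 249 ± 5.42 TPM and GDF15 at 409 ± 0.24 TPM. Of 29 trophectoderm and cytotrophoblast genes 26 reached 10 TPM, as did 28 of 30 syncytiotrophoblast, 17 of 29 extravillous trophoblast and 24 of 25 G2/M and mitosis genes. Of 24 primed pluripotency genes 5 did, and 0 of 18 primitive streak and mesoderm and 0 of 19 neuroectoderm genes did.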

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

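The tests of an extra copy of chromosome 12, of a rise of chromosome 12 genes wherever TP53 was lost, and of a lower yield of long transcripts were chosen after the result was seen.

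Results of this kind are those whose TP53KO effect differed between stages. The TP53KO effect at D7 differed from that in EPSC, by the edgeR test of the difference, for 2066 genes. By camera, the lists that differed were G2/M and mitosis (median difference 0.89), G1/S and replication (0.31), naive pluripotency (-1.14), trophectoderm and cytotrophoblast (-0.61), syncytiotrophoblast (-2.47, with 14 of 26 genes at 0 counts in an EPSC group), extravillous trophoblast (-0.41), ATF4 and unfolded protein response (-0.44), mitochondrial transcripts (-1.29) and ribosomal proteins (0.41). With an estimated correlation camera called only G2/M and mitosis and syncytiotrophoblast (adjusted p = 0.0125 for both), and the others had an adjusted p of 0.092 to 0.46. Among named genes the difference in log2 was 0.97 for TP53, 2.54 for CDKN1A, -2.34 for PGF, 1.16 for TPX2, 1.29 for BUB1, -3.46 for SFRP2, 2.05 for POU5F1, -2.68 for KLF4, -1.68 for KRT7 and -6.85 for HSD11B2. It was -2.24 for SDC1, -2.33 for FN1, -1.86 for FLT1, 1.97 for NES, -2.72 for EGLN3, -1.91 for ATF3, -1.67 for CEBPB, -3.51 for PHLDA2, -2.23 for CDKN1C and -7.65 for INPP5D.

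Between EPSC or D7 and EVT cells, lists and genes called in opposite directions differed without a test of the difference. Naive pluripotency had a median of 0.35 in EPSC and -1.41 at EVT D3, epithelial junctions -0.33 at D7 and 0.19 at EVT D6, and ATF4 and unfolded protein response 0.38 in EPSC and -0.87 at EVT D3. Mitochondrial transcripts had -1.145 at D7 and 0.33 at EVT D6, and ribosomal proteins -0.20 in EPSC, 0.32 at EVT D3 and 0.40 at EVT D6. None of these list calls held with an estimated correlation (limma's camera, adjusted p = 0.195 to 0.721), and several ended when a library was left out: naive pluripotency in EPSC and epithelial junctions at D7 without any single library of their 4, ATF4 in EPSC without WT replicate 1 and ribosomal proteins in EPSC without WT replicate 2. CLDN3 changed by -0.99 at D7, 1.24 at EVT D3 and 1.83 at EVT D6, and FN1 by 0.76 in EPSC and -1.40 at EVT D6. FN1 did not pass in EPSC when the EPSC libraries were fitted alone or without TP53KO replicate 1.

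Chromosome 12 genes were higher in TP53KO EPSC and D7, with 92.0% and 86.1% of those with at least 5 CPM above 0 against 44.9% and 46.9% of other genes. Sets of genes from other autosomes matched on transcript length, GC content and level reached a median of at most 0.0575, which argues against these properties, and the median at EVT D3 and EVT D6 reached at most 0.0444, which argues against a rise of these genes wherever TP53 was lost. The lowest of 14 windows along the chromosome had a median of 0.338 over EPSC and D7, so the rise ran along the whole chromosome. Windows of other autosomes had medians of -0.2528 to 0.3266 in EPSC and -0.3867 to 0.6048 at D7. Single windows elsewhere at D7 thus reached the range of the chromosome 12 windows (0.3593 to 0.9047). An extra copy of chromosome 12 in the TP53KO cells used for EPSC and D7 is therefore a candidate explanation, with medians per TP53KO library of 0.414, 0.417, 0.531 and 0.485 beside 0.585 for 3 copies over 2. No DNA was measured, and a gain in part of the cells stays open.

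WT EPSC replicate 2 stood apart from the other EPSC libraries, with a correlation across genes of 0.982 with WT replicate 1 against 0.994 between the TP53KO replicates. Its 10 most abundant genes took 8.58% of counts, 0.66 percentage points from the nearest other EPSC library, which argues against a few genes taking most of the counts. Across genes, Spearman's rho of transcript length with the log2 ratio of replicate 2 to replicate 1 was -0.398, against -0.262, 0.139 and -0.193 in the other replicate pairs of the same table (genes are not independent replicates). A lower yield of long transcripts in replicate 2 is therefore a candidate explanation, with a median ratio of 0.151 in the shortest and -0.168 in the longest genes of 3 equal classes. Spearman's rho of GC content with the same ratio was -0.298, and length and GC content were not separated. WT replicate 1 correlated at 0.9835 and 0.9853 with the TP53KO EPSC libraries, so it lay closer to them than to WT replicate 2 (0.9821). No biological explanation was tested, and the shared WT EPSC label does not exclude one.

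G2/M and mitosis genes were higher in TP53KO at D7, EVT D3 and EVT D6 (medians 0.85, 0.88 and 1.78; limma's camera with an estimated correlation, adjusted p = 0.00774, 0.176 and 0.204). Undifferentiated cells left in the D7 cultures would need a median share of 19.9% (9.61% to 47.8% over genes) to give the G2/M levels, while primed pluripotency genes allowed a median of 0.352% (0.014% to 62.7%), which argues against them. Other scalings gave medians of at least 0.857, and a factor per library moves all genes alike while camera set these genes against all others (adjusted p = 6.24e-14 at D7), which argues against scaling. Only 1 of the 25 genes, FOXM1, lies on chromosome 12, so the median of 0.8505 outside it at D7 was bound to stay close, and an effect of that chromosome on genes elsewhere was not tested. Loss of TP53, the difference the design names, may account for the rise, a hypothesis found and tested on the same data. In EPSC, where TP53 was also lost, the G2/M median was 0.0084 and 2 of 25 genes rose (camera adjusted p = 0.75). Loss of TP53 thus did not go with a rise of the list at every stage. The share of undifferentiated cells was worked out for D7 only. Undifferentiated TSC left in the EVT cultures and a shift in the mix of differentiated cell types were not tested.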

How the results depend on the processing

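Library total scaling, leaving out chromosome 12 genes and every setting of the 4-comparison overlap were chosen after the result was seen, and all other alternatives before the data were examined. With a single library left in a group, it was assumed to vary like the other groups. No alternative reversed the direction of a gene named in a comparison of the report or of the other observations.

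A log2 change of at least 1, a stricter threshold by construction, left 249 genes in EPSC, 1738 at D7, 1125 for the difference of effects, 2295 at EVT D3, 1563 at EVT D6 and 19 in the overlap of 4 comparisons. Without chromosome 12 genes 646 genes were called in EPSC and 87 in the overlap, and the other comparisons and the 61 list calls of 140 stayed within 1.5 times. With only the EPSC libraries fitted, 202 genes were called in EPSC, of which 198 were among the 1053. The D7 libraries fitted alone gave 6580 genes at D7 in place of 4832. The joint fit pools the spread of its groups, and WT EPSC replicates varied most (mean chi-squared per gene 20.6, others 2.85 to 6.47). WT EPSC was thus judged in part by the smaller spread of other groups, so the joint EPSC count may be too high. How much of the difference this explains was not tested. With only the groups compared, the list calls on BMP and TGF-beta targets in EPSC and on G1/S and replication, primed pluripotency, primitive streak and mesoderm and epithelial junctions at D7 ended. Leaving out single libraries gave 170 to 4500 genes in EPSC, 2615 to 3480 at D7, 1086 to 4570 for the difference of effects, 11108 to 13126 for WT D7 against WT EPSC, 6882 to 7000 at EVT D3 and 5649 to 5877 at EVT D6; beyond the loss of samples the cause was not tested.

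The replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at -0.016 to 0.039 across genes. A replicate block gave 1784 genes in EPSC, 5219 at D7, 2557 for the difference of effects, 12280 for WT D7 against WT EPSC, 7870 at EVT D3, 6744 at EVT D6 and 190 in the overlap, and the D7 calls on G1/S and replication, primed pluripotency, primitive streak and mesoderm, epithelial junctions and ribosomal proteins ended.

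With an estimated correlation camera called 12 lists of 140 in place of 61, and fry, which does not set a list against other genes, called 88. The estimated form has few degrees of freedom, so its p values rose even for lists with a correlation below the preset. TP53 targets at EVT D6 (correlation -0.013) went from camera adjusted p = 3.46e-14 to 0.204, and G2/M at EVT D3 (-0.012) from 7.04e-08 to 0.176. For such lists the loss does not show that correlation between genes undid the call. For lists above the preset, such as ribosomal proteins in EPSC (0.782), the share due to correlation was not tested. Among lists that camera or fry called, fry's direction was opposite to camera's for mesenchyme and EMT at D7 (median -0.11, fry adjusted p = 0.041), imprinted placental genes at D7 (0.14, 0.0314) and hypoxia and glycolysis in WT D7 against WT EPSC (-0.000896, 0.000697). Directions also differed for some lists that neither called, such as apoptosis machinery in EPSC.

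DESeq2 gave 1006, 4010, 1815, 5843 and 5131 genes in EPSC, at D7, for the difference of effects, at EVT D3 and at EVT D6, and no filter 1567 in EPSC. Library total scaling reversed the sign of 501 EVT D3 calls and quantile normalisation of 318. Of named genes 13 of 45 in EPSC lost their call under a setting, 1 of 61 at D7 (MRGPRX1) and 1 of 60 at EVT D3 (EGR1). In simulated data with the same pooled dispersion for both, a log2 change of 1 was recovered for 93% of genes in EPSC and 86% at D7. Smaller changes were not simulated, so the reach of 2 libraries per group for them was not measured.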

Other observations

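FOSL1, FOSB, JUNB and EGR1, transcription factor genes that growth factor signals are known to induce, were lower in TP53KO in all 4 comparisons. FOSL1 changed by -2.96 in EPSC, -2.45 at D7, -1.12 at EVT D3 and -1.54 at EVT D6, FOSB by -1.31, -4.27, -0.84 and -0.75, JUNB by -0.78, -1.02, -1.41 and -1.19, and EGR1 by -0.98, -0.90, -0.80 and -1.07. These 4 genes were chosen after their values were seen, from the 70 that fell in each comparison, and no list of such genes was tested. JUNB did not pass in EPSC when the EPSC libraries were fitted alone or without either TP53KO replicate. EGR1 did not pass at EVT D3 in DESeq2, with library total scaling or without TP53KO replicate 2 or WT replicate 2.

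Zinc finger genes of a cluster on chromosome 19 (19900000 to 24300000, GRCh38), a region chosen after its values were seen, were counted without a test of the group. In EPSC 10 of its 32 tested ZNF genes rose and 0 fell, with a median of 0.35, against 6 rises and 3 falls among 417 other ZNF genes. At D7 20 of 32 rose and 0 fell (median 0.64), against 74 rises and 25 falls of 417. At EVT D3 16 of 31 rose and 1 fell (median 0.58), against 99 rises and 59 falls of 388. At EVT D6 6 of 31 rose and 1 fell (median 0.07), against 44 rises and 83 falls of 394. Members of the cluster are similar in sequence, so reads shared between them leave the count of rises uncertain.

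Across genes, Spearman's rho of GC content with the log2 ratio of replicate 2 to replicate 1 was 0.561 in TP53KO D7, -0.298 in WT EPSC, 0.214 in TP53KO EPSC and -0.097 in WT D7. Whether the trend between the TP53KO D7 replicates affected the D7 comparison was not tested.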
